A study of Mus musculus with 2 samples.

How the data were processed

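The data were droplet single-cell RNA-seq libraries of sorted cells from embryonic mouse brain, 1 library per condition. Per the labels' protocols, 8834 control and 9055 stressed cells were sorted, about 6000 were loaded for 10x Genomics Chromium 3′ libraries of v3 chemistry, and 1156 and 1467 were recovered, which equals the numbers of barcodes in the files. The deposited values are raw UMI counts per gene and barcode. Their software version is 3.0.0, per the file headers. Cell Ranger 3.0.0, STAR, Seurat 2.4 and the mouse assembly GRCm38.p5 (mm10) are named per the submitters' processing notes, without the role of each. The files hold called cells only, so free RNA in empty droplets was not analysed here, and no cell annotation of the authors was used.

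All 31053 features were read, and of features that share a symbol the one with most UMIs kept the plain symbol. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept: 88 control and 48 stressed barcodes had fewer genes and 1 and 21 exceeded the mitochondrial limit. Both libraries were clustered together with scanpy 1.11.5 (Python 3.11.15, igraph 0.11.9): counts scaled to 10000 per cell and log-transformed, 2000 variable genes without Xist, Tsix and Y-linked genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. Clusters were named from marker lists written before the data were examined. The microglia-like class joined 3 clusters, led by Gpnmb and Csf1, by Mki67 and Ndc80, and by Slc2a5 and Tmem119, and these held similar parts of the class in both libraries (36.4% and 32.4%, 16.7% and 19.2%, 47.0% and 48.4%). Scrublet scored doublets per library. Its own threshold marked 3 control and 2 stressed cells, so the alternative without doublets removed the highest 3.5% of scores (37 and 49 cells), in the range estimated in the submitters' design text. Doublets were kept otherwise.

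Raw counts were summed over the cells of a class in each library and divided by the class total to give CPM. Log2 ratios are stressed over control, with exact conditional intervals. Sums have exact Poisson intervals and shares exact Clopper-Pearson binomial intervals, all at 95%. Intervals cover counting error only: they leave out differences between cells, embryos, litters and libraries, so they are too narrow as errors of a condition. At 50 CPM a gene has about 91.5 UMIs in the control and 258 UMIs in the stressed sum. A sum of 0 was set to 3 counts for a ratio, and a share of 0 allows up to 3 cells of the total. Ribosomal, mitochondrial, haemoglobin and sex-linked genes were left out of the count of genes. Gene lists were fixed before the data were examined, with members of at least 10 CPM measured and called higher or lower at 1.5 times, and their medians were placed among 10000 random lists matched in 20 expression bins. For shares of cells with a UMI, each cell was thinned to 1100 UMIs, the 10th percentile of the control microglia-like cells rounded down.

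Genes were named by a rule written before the data were examined: 16 genes always, the 12 highest and 12 lowest log2 ratios at 50 CPM, and up to 4 members of each list with the largest ratios. Genes named in other cell classes, and other exceptions, were chosen after their values were seen. A few genes that the rule takes are not reported here. Gene positions come from the GENCODE M21 annotation of GRCm38, in which 31011 of the 31053 feature identifiers were found. The count step was tested on simulated counts for whole libraries with 2481 genes: all 50 genes set 3 times higher and all 49 set 3 times lower passed 2 times, none of the 50 set 1.5 times higher nor the 49 set 1.5 times lower did, and 0 of 2283 unchanged genes did. Intervals covered the true ratio in 95.3% of unchanged genes and in 88 to 95.9% of the changed sets. The simulation holds counting error alone.

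Alternatives for microglia-like values were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors, the mean of per-cell CPM, thinned cells, a filter of 1000 genes and 5% mitochondrial UMIs, doublets removed, Leiden resolution 1.0, non-cycling cells, cells with less dissociation response, and female cells. Counts were also made at 20 and 100 CPM, without a CPM minimum and at 1.5 times. Male cells could not be compared. Alternatives chosen after seeing the data were control cells without Xist against stressed female cells, sums without the 1% of cells with most UMIs of each gene, and the border-associated share among female cells. Figures were drawn with matplotlib 3.10.9.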

Results

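Single-cell transcriptomes were collected from the hypothalamic and thalamic region of mouse embryos of the outbred CD1 strain at E15.5. Cells positive for both Cd11b and Cd45, surface proteins of myeloid and blood-derived cells, had been sorted by flow cytometry before droplet capture. The control library came from 10 embryos of 1 dam, and the stressed library from 5 embryos of 1 dam kept at 4 °C for 30 min per day from E11.5 to E15.5. The files held 1156 barcodes and 2833015 UMIs (unique molecules counted) for the control library, with a median of 1948 UMIs and 945 genes per barcode. The stressed library held 1467 barcodes and 6582188 UMIs, with a median of 3767 UMIs and 1452 genes. Each condition was 1 pool of embryos in 1 library. No test between conditions was therefore possible, the differences have no replicate check, and every interval given is a 95% interval that covers counting error only.

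The first comparison asked which cells the sort had delivered from each pool. Microglia-like cells, the resident macrophages of the brain, made up 65.2% of the cells kept in the control library (696 of 1068, exact binomial interval 62.2 to 68.0%) and 81.6% in the stressed library (1148 of 1407, 79.5 to 83.6%). Border-associated macrophage-like cells, led by Lyve1, Cd163, Pf4 and F13a1, accounted for 7.30% of the control cells (78 cells, 5.82 to 9.03%) and 2.06% of the stressed cells (29 cells, 1.38 to 2.95%). Among macrophages of both kinds, the border-associated share was 10.1% (8.05 to 12.4%) in the control library and 2.46% (1.66 to 3.52%) in the stressed library. Neural-like cells, led by Six3, Dlx1 and Sox11, made up 20.3% (217 cells) and 12.5% (176 cells), although such cells lack both sorted proteins. Monocyte or granulocyte-like cells with S100a8, S100a9 and Ly6c2 made up 3.00% and 1.92%. A cluster led by haemoglobin genes with vascular genes such as Cldn5 and Rgs5 was left unnamed and held 4.21% and 1.92%. Shares can be set by the dissection, the sort gate and the gap in depth between the libraries.

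**Figure D1:**
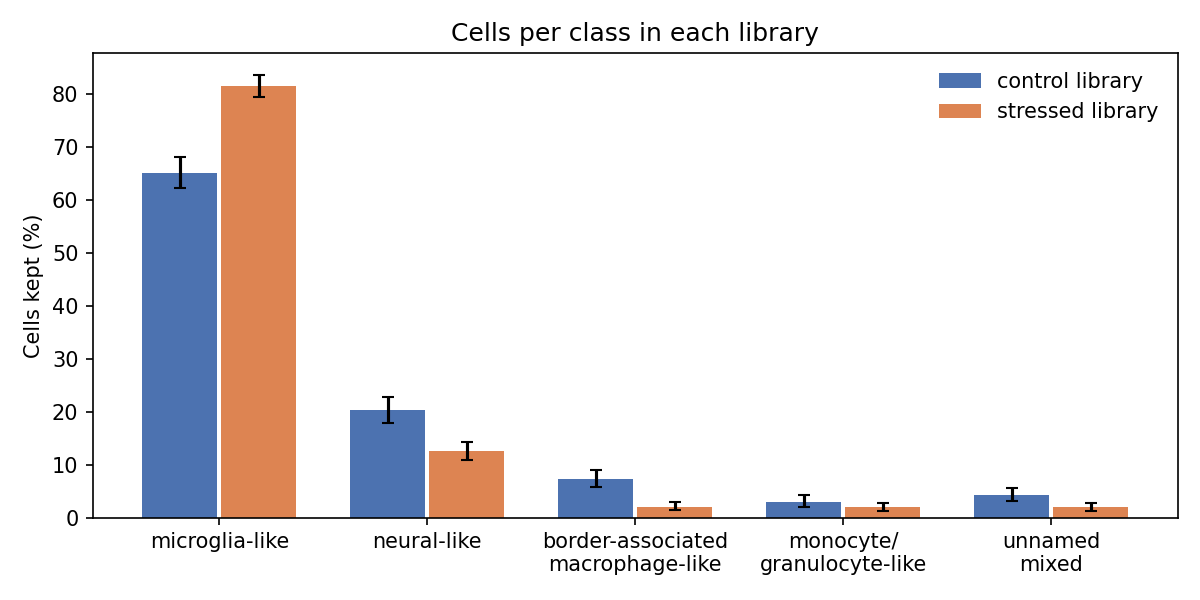
Percent of the cells kept (vertical axis) in each class (horizontal axis) for the control and stressed libraries, 1 library each, with exact binomial 95% intervals that cover counting error only. Microglia-like cells made up 65.2% of the control and 81.6% of the stressed library, and border-associated macrophage-like cells 7.30% and 2.06%.

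The sex of the embryos was read from sex-linked transcripts, because pools of 10 and 5 embryos can differ in it. In microglia-like cells, Xist, the RNA that coats the inactive X chromosome of females, stood at 537 CPM (UMIs scaled to the total of the class, exact Poisson interval 504 to 571) in the control library and 1809 CPM (1773 to 1846) in the stressed library. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together gave 182 UMIs, or 99.5 CPM (85.5 to 115), in the control library and 1 UMI, or 0.194 CPM (0.00490 to 1.08), in the stressed library. After each cell was thinned to 1100 UMIs, 26.6% of control cells (23.2 to 30.1%) and 77.8% of stressed cells (75.3 to 80.2%) had Xist only. Y transcripts alone were found in 9.63% of control cells (62 of 644) and in 0 of 1143 stressed cells, which allows a share with such a transcript found of up to 0.262%. This limit is on detection and not on male cells, since 63.7% of control cells had neither Xist nor Y transcripts at this depth. Without thinning, Xist was detected in 33.6% and 92.3% of cells. The same difference held in the other classes: neural-like cells had 36 Y-linked UMIs in the control library and 0 in the stressed library, and border-associated cells 28 and 0. Y-linked transcripts at 0.194 CPM, against 99.5 CPM in the control library, argue against more than a small part of male cells in the stressed pool. Of the 696 control microglia-like cells, 135 had Y transcripts without Xist and 462 had no Xist detected. The libraries thus differed in sex make-up as well as in maternal treatment. The named genes were therefore also compared among cells with Xist and no Y transcript, which are called female cells here. There were 230 such microglia-like cells in the control library and 1059 in the stressed library. No stressed microglia-like cell had Y transcripts without Xist, so a comparison of male cells gave no value.

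**Figure D2:**
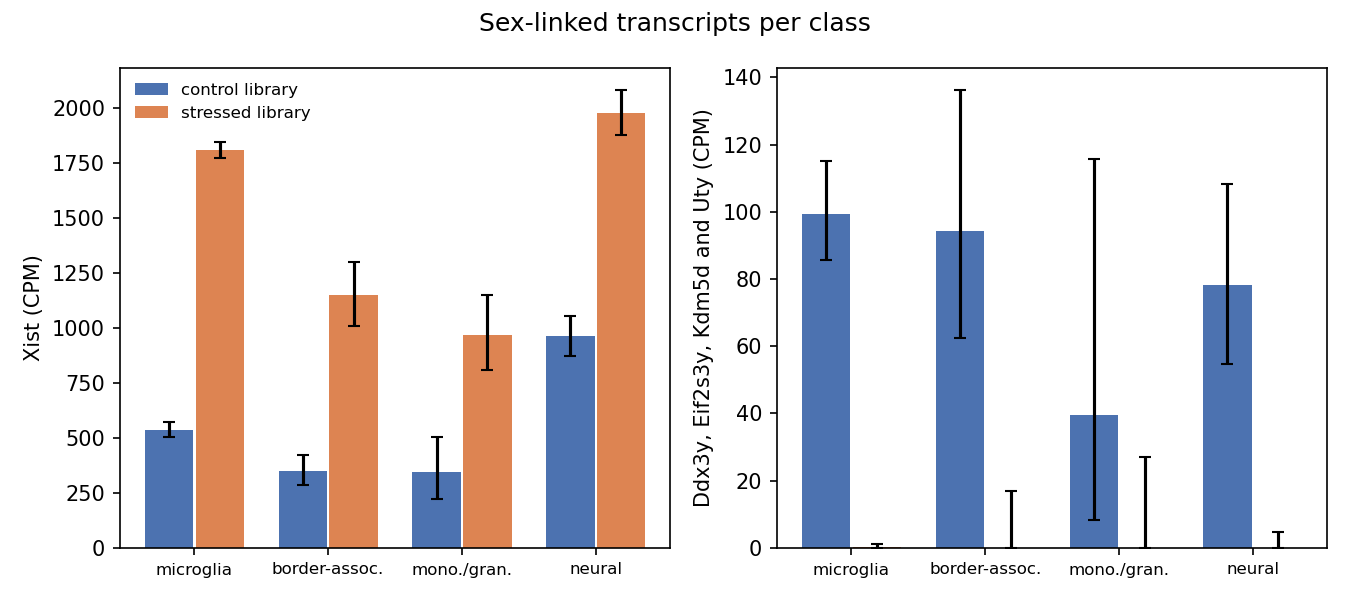
CPM of Xist (left vertical axis) and of 4 Y-linked genes summed (right vertical axis) in 4 cell classes (horizontal axis) of the control and stressed libraries, 1 library each, with exact Poisson 95% intervals for counting error. In microglia-like cells Xist stood at 537 and 1809 CPM, and the Y-linked genes at 99.5 and 0.194 CPM.

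The main comparison asked how transcript levels in microglia-like cells differed between the pools, from 1829964 control and 5164175 stressed UMIs. The abundant transcripts Spp1 (osteopontin, a secreted glycoprotein) and Ctsb (the lysosomal protease cathepsin B) were lower in the stressed library. Spp1 stood at 5666 CPM (5558 to 5776) in the control library and 2455 CPM (2412 to 2498) in the stressed library, a log2 ratio of −1.21 (−1.24 to −1.17). Ctsb stood at 4851 CPM (4751 to 4953) and 2055 CPM (2016 to 2094), a log2 ratio of −1.24 (−1.28 to −1.20). Lgals3, which encodes galectin 3, had a log2 ratio of −1.29 (−1.56 to −1.02), and Gpnmb, a membrane glycoprotein of activated phagocytes, one of −1.19 (−1.47 to −0.90). Lgals3 was at −0.98 with the mean of per-cell CPM, −0.66 with thinned cells and −0.80 in non-cycling cells. Emid1 was the gene with the highest ratio: it had 10 UMIs in the control library and 405 in the stressed library, a log2 ratio of 3.84 (2.95 to 4.91).

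Of 2567 genes with at least 50 CPM in a library, 10 were at least 2 times higher and 14 at least 2 times lower in the stressed library, and 96.3% lay within 1.5 times. The median log2 ratio of these genes was −0.07, and TMM scaling raised it by 0.11, so smaller differences depend on the scaling. Above Lepr, the leptin receptor gene (121 and 343 CPM, log2 ratio 1.51), only Emid1 and the histone gene Hist1h2ae (1.62) had higher ratios. The others at least 2 times higher included Gm8186 (1.48), Gm10260 (1.44), Rpl27-ps3 (1.33), Sft2d1 (1.28), Rbmxl1 (1.24) and Prps2 (1.06), and Npl (0.94) and Eef1b2 (0.84) were also among the 12 highest. On the lower side stood Qsox1, a sulfhydryl oxidase gene (−2.66), Slpi, a secreted protease inhibitor gene (−2.56), Ldhb, a lactate dehydrogenase subunit gene (−2.16), Sag (−1.73), Dennd5b (−1.72), Gm8797 (−1.50), Dynlt1f (−1.45) and Slc44a2 (−1.09), besides the 4 named above. Vim (−1.06) and Nme2 (−1.01) were the remaining genes past 2 times lower and were named after their values were seen. Gm8186, Gm10260, Rpl27-ps3, Gm8797, Rbmxl1, Dynlt1f, Hist1h2ae and Eef1b2 have close copies elsewhere in the genome and Lepr overlaps Leprot, so their counts are uncertain. A few cells held much of the sum of some genes: the 1% of cells with most of the gene's UMIs held 79.0% of the control UMIs of Slpi, 53.4% of those of Lgals3 and 61.1% of those of Lepr, against 18.2% for Spp1 and 4.54% for Ctsb. The cluster of the class led by Gpnmb, Csf1, Spp1, Ccl4 and Ccl3 held 36.4% of it in the control and 32.4% in the stressed library.

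Among female cells the log2 ratios were −1.32 for Spp1, −1.20 for Ctsb, −1.20 for Lgals3, −2.69 for Qsox1, −2.28 for Ldhb, 4.03 for Emid1 and 1.58 for Lepr. Slpi moved to −0.94 (−1.64 to −0.18), Gpnmb to −0.84 (−1.29 to −0.37) and the X-linked gene Prps2 to 0.25 (−0.22 to 0.76). Prps2 also lay under 2 times with thinned cells (0.79), the stricter cell filter, non-cycling cells and less dissociation response. Slc44a2 lay past 2 times in 8 of 12 alternatives, Gpnmb in 10 and Rbmxl1 in 11. In the GRCm38 assembly Spp1 (ENSMUSG00000029304) spans chromosome 5 from 104435118 to 104441050, Ctsb (ENSMUSG00000021939) chromosome 14 from 63122462 to 63145923 and Emid1 (ENSMUSG00000034164) chromosome 11 from 5106265 to 5152257. Lepr (ENSMUSG00000057722) spans chromosome 4 from 101717404 to 101815352, Qsox1 (ENSMUSG00000033684) chromosome 1 from 155776029 to 155812889 and Ldhb (ENSMUSG00000030246) chromosome 6 from 142490249 to 142507957. These are whole-gene spans, and 3′ tags do not show which exon was read.

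**Figure D3:**
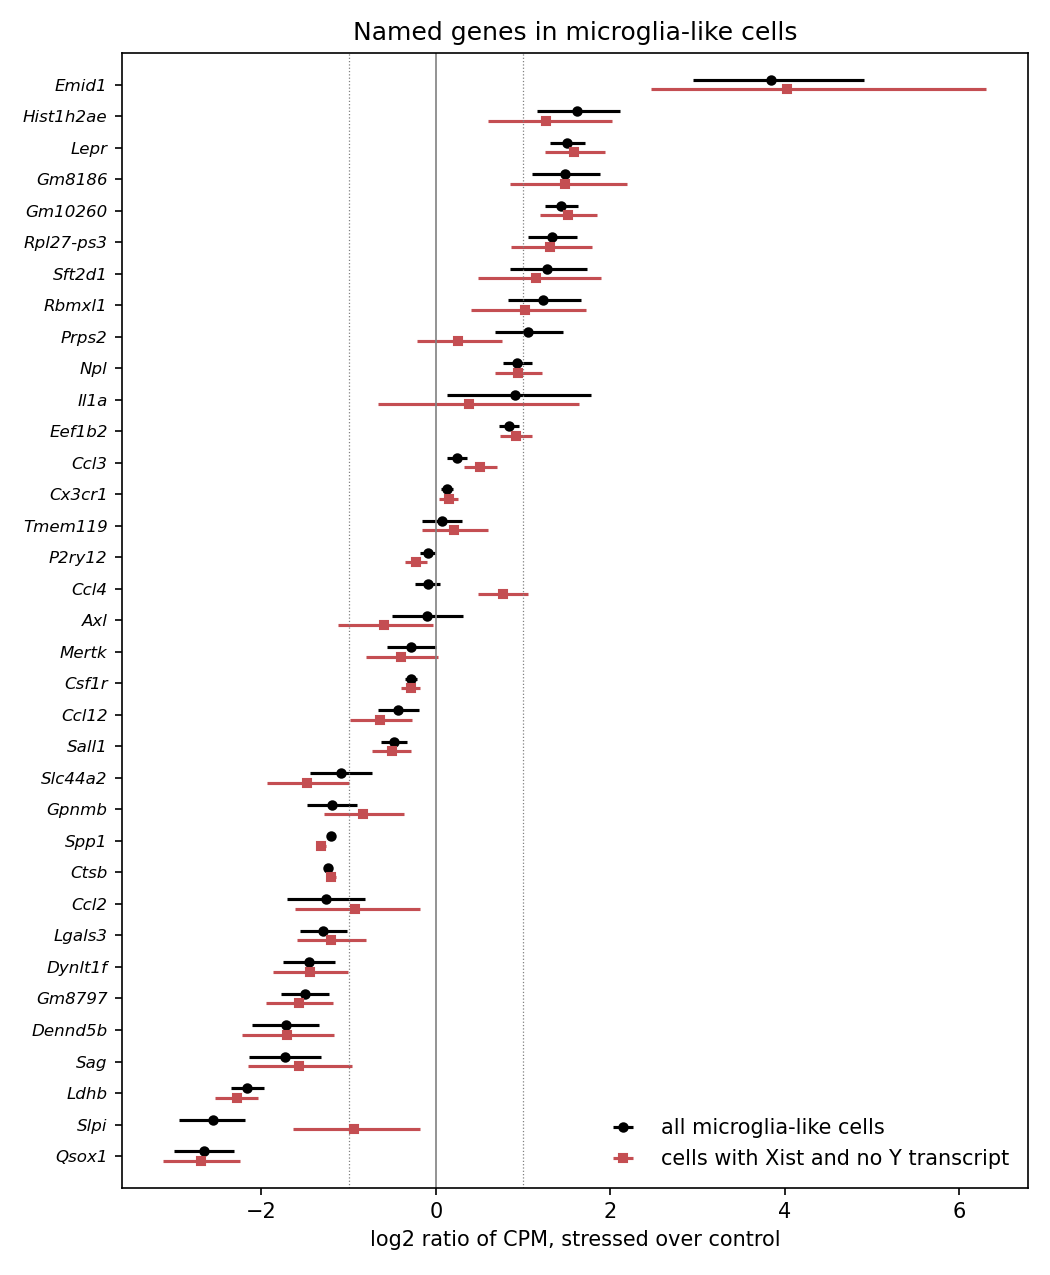
Log2 ratio of CPM, stressed over control (horizontal axis), of genes named by size and of always-named genes with at least 10 CPM in a library (vertical axis), in all microglia-like cells (circles) and in cells with Xist and no Y transcript (squares). With exact 95% intervals for counting error as bars, 1 library per condition and dotted lines at 2 times, Spp1 and Ctsb lie between −1.32 and −1.20 in both sets, while Ccl4 lies at −0.10 and 0.77.

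Chemokines were examined because microglia can release them on stimulation. Ccl3 stood at 471 CPM (440 to 503) in the control and 557 CPM (536 to 577) in the stressed library, a log2 ratio of 0.24 (0.13 to 0.35), and Ccl4 at 310 CPM (285 to 336) and 290 CPM (276 to 305), a ratio of −0.10 (−0.24 to 0.05) that was 0.01 with TMM scaling. Ccl2 (43.2 and 18.0 CPM, −1.26), Ccl12 (−0.43), Ccl6 (−0.56) and Ccl9 (−0.60) were lower in the stressed library. Among female cells the log2 ratio was 0.51 (0.32 to 0.70) for Ccl3 and 0.77 (0.49 to 1.06) for Ccl4, which turned the direction of Ccl4, and −0.93 for Ccl2. Of the control UMIs of Ccl4, 42.9% lay in 7 cells. At equal depth a Ccl3 UMI was found in 23.3% of control cells (20.1 to 26.8%) and 22.1% of stressed cells (19.8 to 24.7%), and a Ccl4 UMI in 8.23% (6.23 to 10.6%) and 8.14% (6.62 to 9.88%). These shares left out 52 control and 5 stressed cells with under 1100 UMIs, and without thinning they were 34.3% and 39.9% for Ccl3 and 13.1% and 15.3% for Ccl4. In neural-like cells, taken as background, thinned shares were 0% (0 of 173, up to 1.73%) and 2.45% for Ccl3 and 1.73% and 1.84% for Ccl4, with median depths of 1546 and 3229 UMIs against 2167 and 3899 UMIs in microglia-like cells. Tnf (4.92 and 5.62 CPM) and Il1b (2 and 5 UMIs) were near the counting limit, and Cxcl10 had no UMI in either library. Il1a had 16 and 85 UMIs, or 8.74 and 16.5 CPM, a log2 ratio of 0.91 (0.13 to 1.78) that was 0.38 among female cells.

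As a list, the genes of resting microglia differed little. All 20 measured members of the homeostatic list lay within 1.5 times, with a median log2 ratio of 0.06, at percentile 86.4 of 10000 random lists matched on size and expression. The median was 0.23 (percentile 99.96) with cells of at least 1000 genes and at most 5% mitochondrial UMIs, and 0.12 (percentile 99.03) at Leiden resolution 1.0. P2ry12 (−0.09), Cx3cr1 (0.13), Tmem119 (0.07), Csf1r (−0.28, −0.36 to −0.21) and Sall1 (−0.48, −0.63 to −0.33) were among the 20 members. Crybb1 went the other way (0.47, 0.38 to 0.56), so the median covers members off 0 in both directions. Among female cells 1 of the 20 was higher by 1.5 times and 0 were lower. Axl (−0.10) and Mertk (−0.28), receptors used in clearing dying cells, lay in a phagocytosis list with all 16 members within 1.5 times. Most genes did so, since 96.3% of those with at least 50 CPM lay within 1.5 times, although list members were measured from 10 CPM. Among female cells 1 of 18 measured phagocytosis members was higher and 3 were lower, with Axl at −0.60. Mki67, a marker of dividing cells, had a UMI in 8.07% of control and 6.47% of stressed cells at equal depth, with overlapping intervals, and Top2a in 6.37% and 6.39%.

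Several lists stood apart from random lists in these libraries. Members of random lists were drawn independently of each other, while genes of a real list can vary together. The percentiles therefore describe these libraries and do not measure how unusual a list is between pools. Lower in the stressed library were the chemokines (median −0.50, 2 of 6 lower and 0 higher by 1.5 times, percentile 0.01, but −0.25 and percentile 3.85 with the stricter cell filter) and the amoeboid or activated microglia list (−0.23, 5 of 22 lower, 2 higher, percentile 0.02). So were glycolysis and hypoxia genes (−0.29, 3 of 18 lower, 0 higher, percentile 0.01), with Bnip3 at −0.93 and Slc16a3, a lactate transporter gene, at −0.86. Cholesterol synthesis genes had a median of −0.50 with 3 of 13 lower and 1 higher (percentile 0.165, and 26.9 with thinned cells). Within the amoeboid list Apoe, the apolipoprotein E gene, went the other way, at 5260 and 8203 CPM (log2 ratio 0.64, named after its value was seen). The medians of the mitochondrially encoded genes (0.64, 9 of 13 higher by 1.5 times, percentile 100) and of the ribosomal protein genes (0.23, 9 of 81 higher, percentile 100) lay above 0. Of the mitochondrial genes mt-Nd6, named after its value was seen, did not stand higher (−0.14, −0.41 to 0.13). The mitochondrial list was also higher in neural-like (0.75) and border-associated cells (0.62), as was the ribosomal list (0.32 and 0.13). The median mitochondrial share per barcode was 2.138% in the control and 3.503% in the stressed library. Complement (0.25, 1 of 6 higher, percentile 98.9), oxidative stress response (0.22, 1 of 10 higher, percentile 99.5), immediate early (0.14, 2 of 12 higher, percentile 98.4) and S phase genes (0.05, 2 of 36 higher and 2 lower, percentile 98.5) also lay high among random lists, but none of these 4 did with members of at least 50 CPM. Among the lists that stood apart, the amoeboid, glycolysis and hypoxia, mitochondrial and ribosomal lists did so under every alternative run, and the chemokine, cholesterol, complement, oxidative stress, immediate early and S phase lists did not.

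Among female cells the medians were −0.46 for chemokines, −0.30 for the amoeboid list, −0.31 for glycolysis and hypoxia, 0.68 for mitochondrially encoded and 0.24 for ribosomal protein genes. Immediate early genes had a larger female median, 0.45 with 5 of 11 higher (percentile 99.96), as did cholesterol synthesis genes, −0.71 with 8 of 14 lower. The cholesterol members measured in all cells had only 14 to 78 control UMIs there. Calls among the fewer female cells thus rest on small counts. Complement genes stood at 0.30, oxidative stress genes at 0.22 and S phase genes at 0.15.

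Apart from the sex-linked genes described above, the remaining program lists lay inside the central 95% of random lists, and TMM scaling turned the sign of small negative medians such as that of lysosome genes (0.05). The cold-inducible genes had a median of −0.02, with Rbm3 and Cirbp at 0.00 and −0.02, and heat shock genes one of 0.04. Glucocorticoid targets had a median of 0.06, which turned to −0.22 in female cells (3 of 9 lower), −0.17 with thinned cells and −0.19 with members of at least 50 CPM. None of the 8 heat shock, 5 cold-inducible or 7 glucocorticoid genes measured in all cells passed 1.5 times. Of the 2567 genes with at least 50 CPM, 96.3% also lay within 1.5 times. List members were measured from 10 CPM, so this share is an unlike baseline, and the counts alone do not set the lists apart. The medians were 0.11 for interferon response (1 of 6 higher, 1 lower), 0.13 for antigen presentation (0 of 8 past 1.5 times), −0.19 for the NF-κB response (1 of 13 higher, 3 lower) and −0.05 for cytokines and growth factors (1 of 11 higher, 2 lower). They were −0.06 for lysosome genes (0 of 23 higher, 2 lower) and −0.09 for phagocytosis genes. They were 0.01 for G2/M phase (1 of 47 higher, 1 lower), −0.05 for nuclear oxidative phosphorylation (1 of 85 higher, 1 lower) and −0.11 for endoplasmic reticulum stress genes (1 of 12 higher, 1 lower). Several of these lists left the central 95% under other settings. With members of at least 50 CPM the NF-κB median turned to 0.18 (percentile 98.1) and that of cytokines and growth factors was −0.28 (percentile 0.355). The cytokine list was also at −0.35 in non-cycling cells (percentile 0.37) and −0.28 with the stricter cell filter (percentile 1.5). Without the highest 1% of cells per gene, an alternative chosen after seeing the data, the NF-κB median was −0.24 (percentile 2.02). Antigen presentation genes stood at 0.27 in female cells (percentile 98.1) and between 0.22 and 0.25 in the 3 other settings where they did so. The G2/M median was −0.18 at Leiden resolution 1.0 (percentile 1.66), −0.54 in non-cycling cells, which were chosen by genes of this list (percentile 0.01), 0.13 with TMM scaling (percentile 97.53) and 0.05 without doublets (percentile 98.8), and that of oxidative phosphorylation −0.11 with the stricter filter (percentile 2.5). The interferon median turned to −0.16 in cells with less dissociation response. Neural markers were low in microglia-like sums: neuron markers summed to 38.3 and 38.0 CPM and neural progenitor markers to 53.6 and 47.6 CPM. Border-associated markers summed to 407 and 363 CPM, mostly from Stab1 (506 of 744 and 1249 of 1875 UMIs). The 4 measured border-associated markers had a median log2 ratio of −0.17 in all cells. Among female cells 3 of 5 were lower, with a median of −0.68. Monocyte markers summed to 317 and 404 CPM, mostly from Lyz2 (550 of 580 and 2013 of 2088 UMIs), and lymphocyte markers to 35.5 and 58.7 CPM.

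**Figure D4:**
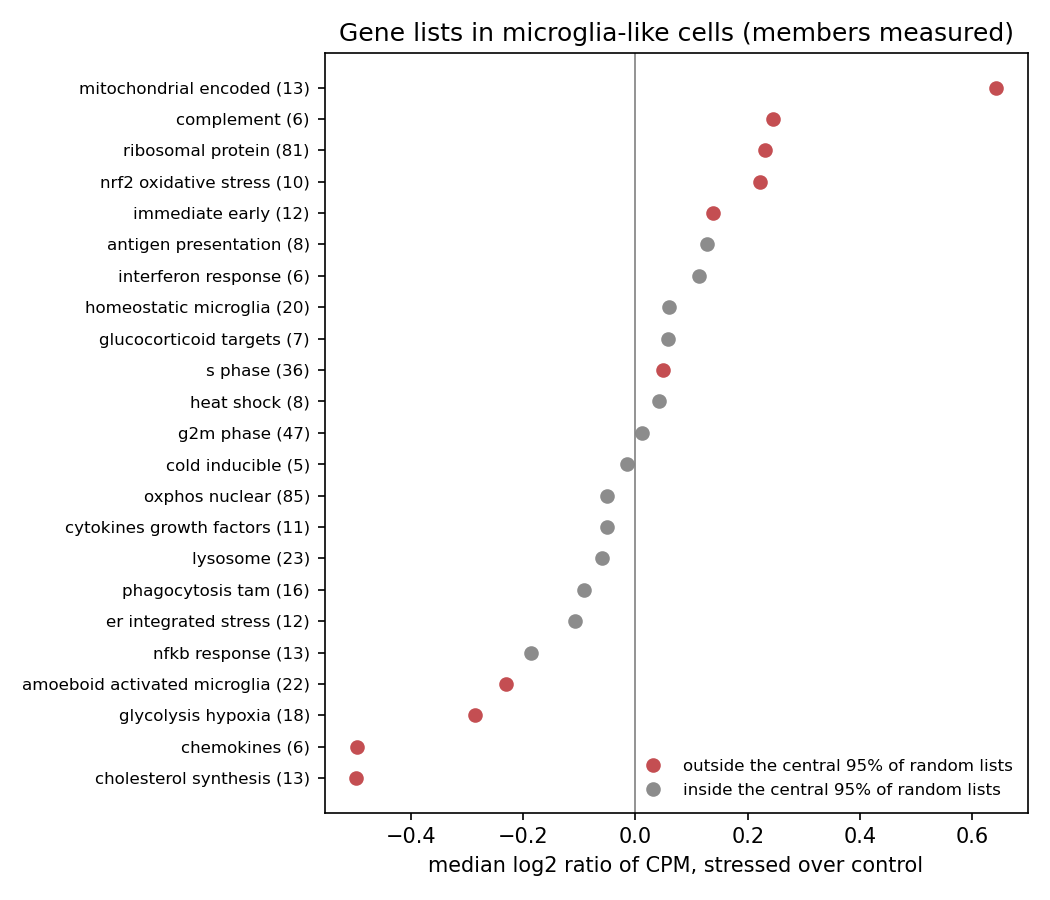
Median log2 ratio of CPM, stressed over control (horizontal axis), of each gene list other than the sex-linked one in microglia-like cells (vertical axis, number of measured members in parentheses), 1 library per condition, coloured by whether it lay outside the central 95% of 10000 matched random lists. Mitochondrially encoded genes lie highest, at 0.64, and chemokines and cholesterol synthesis genes lowest, at −0.50.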

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

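All tests of explanations in this part were chosen only after the results were seen. Ctsb differed in direction between 2 cell classes. Its log2 ratio, stressed over control, was −1.24 in microglia-like and 0.98 (0.57 to 1.40) in neural-like cells. The difference was not tested. Other macrophage transcripts also stood higher in the stressed neural-like cells, with Ctsd at 2.04, Ctsz at 2.08 and C1qb at 3.40. The higher Ctsb value can therefore not be assigned to the neural cells themselves. Markers of microglia summed to 2700 CPM (2585 to 2819) in neural-like cells of the stressed library against 596 CPM in the control library. In monocyte or granulocyte-like cells they summed to 2977 CPM (2695 to 3282) and 1493 CPM, but the make-up of that class differed, with granulocyte markers at 5155 CPM in the stressed and 26130 CPM in the control library. Gnrh1, which encodes the hormone that starts the reproductive axis, was named after its values were seen. It had 566 UMIs in neural-like cells of the stressed library and 0 in the control library, and 564 of them lay in 1 cell, where they were 9.09% of its 6203 UMIs.

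The border-associated share of macrophages was 10.1% in the control and 2.46% in the stressed library. The filter on cells does not account for it, since among all deposited barcodes the shares were 9.71% and 2.44%, with separate intervals. The sex of the pools does not either, since among cells with Xist they were 9.45% and 2.67%, again with separate intervals. Less border and vessel tissue in the stressed dissection cannot be told apart from an effect of maternal cold: of the cells outside the macrophage classes, 15.3% (11.4 to 19.9%) and 11.7% (7.88 to 16.6%) lay in the haemoglobin and vascular cluster, and these intervals overlap, while among all barcodes the order turned (18.7% and 21.1%), as it did with the stricter cell filter (5.43% and 10.2%). That cluster was led by haemoglobin genes, and its median depth was 996 UMIs in the control and 6668 UMIs in the stressed library. Its share therefore cannot show how much border or vessel tissue was taken. Each condition had 1 dam and 1 dissection, so the effect of treatment stays open and untested.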

How the results depend on the processing

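Control cells without Xist and sums without the highest 1% of cells were chosen only after the results were seen. No paired analysis was possible because no test was made and both conditions have 1 library. Male cells could not be compared, since no stressed microglia-like cell had Y transcripts alone. The 10 genes higher and 14 lower became 18 and 29 with thinned cells, 27 and 36 at 20 CPM, 446 and 1081 without a CPM minimum and 23 and 72 at 1.5 times, and 3 genes were higher at 100 CPM. Fewer counts per gene enter the thinned sums, and the other settings change the genes or the threshold. TMM and median-of-ratios factors moved the median of all genes by 0.11 and 0.10 on the log2 scale, from −0.07. With TMM, all 10 higher and 11 of the 14 lower genes stayed past 2 times; among female cells 9 and 11 did. Without the highest 1% of cells per gene, 10 and 10 stayed in the set: Slpi (−1.88), Sag (−1.40) and Dennd5b (−2.15) fell under 50 CPM with ratios still past 2 times, and Vim also left it. None of the genes past 2 times that the rule named changed direction under any alternative run. Of the values of named genes under alternatives, 1151 stayed within the counting interval and 204 did not.

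The S phase median turned from 0.05 to −0.10 under the stricter cell filter and to −0.063 in non-cycling cells, and the oxidative stress median from 0.22 to −0.034 with members of at least 50 CPM. Non-cycling cells were chosen for having no UMI of cycle genes that include the S phase members Pcna and Mcm5. The S phase value in those cells is thus not independent of the choice. Of the lists, 6 lay in the top 2.5% of random lists, and 3 did against control cells without Xist. Microglia-like cells were 69.5% and 81.5% under the stricter filter, control before stressed, and 64.4% and 78.9% of all barcodes. The border-associated share of macrophages was 14.9% and 3.06% under the stricter filter and 7.75% and 1.70% at Leiden resolution 1.0. Ccl3 was found in 32.0% of control and 26.5% of stressed cells when thinned to 1500 UMIs, in 34.3% and 39.9% without thinning, and with at least 2 UMIs in 11.2% and 9.19%. Ccl4 was found in 11.7% and 9.30% at 1500 UMIs, in 13.1% and 15.3% without thinning, in 4.35% and 4.11% with at least 2 UMIs, and in 6.85% and 6.22% with less dissociation response. For all these shifts the cause was not tested.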

Other observations

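All tests in this part were chosen only after the results were seen. In border-associated macrophage-like cells (78 control and 29 stressed cells), the chemokine gene Ccl12 was lower in the stressed library, with 119 and 12 UMIs and a log2 ratio of −2.86 (−3.85 to −2.00). These UMIs came from few cells. At equal depth a Ccl12 UMI was found in 17 of 76 control cells (22.4%, 13.6 to 33.4%) and 2 of 29 stressed cells (6.90%, 0.846 to 22.8%), with overlapping intervals. Genes of microglia stood higher in the stressed border-associated cells, among them Sparc (2.30), P2ry12 (1.62) and Gpr34 (1.58), as did the lipase gene Lpl (3.11). The make-up of the class differed alongside, since border-associated markers summed to 12717 CPM in the control and 8470 CPM in the stressed cells, and microglia markers to 8532 and 11850 CPM. The genes of this and the next paragraph were named after their values were seen, among genes of at least 200 CPM.

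In neural-like cells, Slitrk2, a synaptic adhesion gene, had 134 and 58 UMIs (log2 ratio −1.94), and Spry2, an inhibitor of growth factor signalling, had 210 and 136 UMIs (−1.36). Transcripts of macrophages were higher there in the stressed library, with Apoe at 2.77, C1qb at 3.40 and Tyrobp at 2.63. The make-up of the neural-like class differed alongside. Dlx1, a leading gene of the class, had 94 control and 44 stressed UMIs (log2 ratio −1.83). Neural progenitor markers summed to 6998 CPM in the control and 8742 CPM in the stressed cells, and neuron markers to 3463 and 2974 CPM.

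Only some of the genes at least 2 times apart in microglia-like cells were tested against their values in other classes. Of 6 genes picked by hand as having near-identical copies, 5 differed in the same direction in neural-like cells beyond counting error. Examples were Gm10260 (2.04) and Gm8797 (−2.11). Lepr, outside these 6, did so in border-associated cells (1.53, 0.85 to 2.25). Litter genotype or the assignment of shared reads is thus a candidate explanation for the 5. Macrophage transcripts also stood higher in the stressed neural-like cells, so agreement there of genes higher in microglia-like cells is not independent. For Ctsb the log2 ratio in border-associated cells was −0.33 (−0.51 to −0.15), in the same direction as in microglia-like cells (−1.24) but smaller. This argues against an effect of equal size in every cell type and leaves a smaller shared decrease open. The make-up of the border-associated class also differed between the libraries. Sex and depth are argued against as the whole cause for Ctsb and Spp1: the ratios were −1.20 and −1.32 among female cells and −1.25 and −1.09 with thinned cells. Maternal cold and any other difference between the litters stay open, since the design confounds them.

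The direction of Ccl4 turned between all microglia-like cells (−0.10) and female cells (0.77). A few cells may account for this: 42.9% of the control Ccl4 UMIs lay in 7 cells, of which 6 had no Xist. More Ccl4 in male cells in general cannot be told apart from this, since at equal depth 8.86% of control cells without Xist (6.34 to 12.0%) and 7.11% of those with it (4.03 to 11.45%) had a Ccl4 UMI, and these intervals overlap. Embryos were not tracked, so a single embryo remains an open source.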
